A study of Mus musculus with 12 samples.

How the data were processed

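RNA abundance was measured in 4 mouse sample types on 2-colour Agilent arrays, with 3 arrays per type and 12 in all. The types were whole embryos and placentas at embryonic day 12.5 (E12.5), embryonic stem (ES) cells, which derive from the inner cell mass, and trophoblast stem (TS) cells, which derive from the trophoblast lineage that builds the placenta. Per the labels, embryos of a litter were combined in one tube and placentas in another, with 5 pooled for replicates 1 and 2 and 3 pooled for replicate 3. The ES cells were of the R1 line, grown on gelatin and marked p12, and the TS cells were of a GFP-Exe line, marked p28/4 for replicates 1 and 2 and p35/22 for replicate 3. Total RNA was amplified and labelled with Cy3, and a common reference RNA pooled from 11 mouse cell lines carried Cy5 on every array. No array had the dyes exchanged, so a dye bias of a probe remains in its ratio, and bounds computed from Cy3 alone are open to it. Differences between groups are free of it only as far as it was equal on all arrays.

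The deposited scanner tables hold fluorescence intensity per spot in both channels with local background, per the file headers, and were produced with Agilent Feature Extraction A.7.5.1. Their processed signals are in intensity units and were corrected by the authors' software for background with spatial detrending and for dye with a linear factor and a LOWESS curve. At 49.1% of spots on the first array that curve moved the Cy3 signal by more than 1% from the linear factor. The deposited value table is in log10 units. Its values followed, within 0.02 for 86.8% to 87.9% of the values per array, the log10 processed Cy3 signal minus the log10 processed Cy5 signal plus the mean log10 processed Cy5 signal of the spot over the 12 arrays. Column medians were 2.97, 2.97 and 2.97 for the embryo arrays, 2.96, 2.96 and 2.95 for the placenta arrays, 2.94, 2.94 and 2.95 for the ES arrays and 2.94, 2.94 and 2.94 for the TS arrays. The scale and the direction of that table follow from this relation, while the centring of the values outside the tolerance stays unknown. It was used only as an alternative.

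Each array held 43430 spots, of which 41034 were not controls and stood for 41006 probes. Mean spot signals were corrected for local background by the normexp method with an offset of 50, turned into log2 ratios of Cy3 over Cy5, and normalised within each array by a loess curve with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform or as population outliers were left out, 9 to 156 per array, and spots of one probe were averaged. Figures were drawn with matplotlib 3.10.9. The files pair probes with transcript accessions. Through the gene table of assembly GRCm38.p6, used for names alone, 15294 probes matched a RefSeq transcript and 110 an accession listed as a synonym, so that 15404 probes named 12338 genes and 25602 probes stayed without a name. For the 2807 genes with more than 1 probe, the probe with the highest mean signal stood for the gene.

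Group means were fitted with limma over all 12 arrays with 1 shared estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all probes of a comparison at a threshold of 0.05. The comparisons were TS cells with ES cells, placenta with embryo, ES cells with embryo, TS cells with placenta, and the interaction, which is the TS minus ES difference less the placenta minus embryo difference. The groups, the tests of the comparisons, the gene lists and the alternatives were fixed before the data were examined, and tests chosen later are named where they are given. The 19 gene lists covered pluripotency, trophoblast stem and early trophectoderm, the placental prolactin family, other placental trophoblast genes, maternal decidua with uterine natural killer cells, neural genes, skeletal and cardiac muscle, cartilage with limb and mesenchyme, fibroblast matrix, plasma proteins of fetal liver and yolk sac, erythroid, endothelial, macrophage and leukocyte, primitive and parietal endoderm, imprinted, Hox, cell cycle, FGF and MAP kinase feedback, and sex-linked genes of the X and Y chromosomes. Each list was tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Genes were named by a fixed rule. It took the 8 highest and 8 lowest differences for TS against ES cells and for placenta against embryo, the 6 highest and 6 lowest for the other pairs and the 5 highest and 5 lowest for the interaction. Apart from the interaction it required the brighter group to be well above background on all 3 arrays and the 3 and 3 values not to overlap. To these were added up to 4 members of each list per comparison and a set of anchor genes, of which Nanog, Eomes, Prl3d1, Ascl2, H19 and Xist had no named probe.

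A signal counted as well above background where the scanner software set that mark, at 2.6 standard deviations of the background, and this held for 90.1% to 95.2% of non-control spots in Cy3. Where a probe was under that mark or saturated on all 3 arrays of a group, the difference between 2 groups is given as a bound, from Cy3 signals scaled between arrays. Interactions are given as fitted, with the groups under the mark named. Where this held on some arrays only, their number is given. Array signals carry no counting depth, so the number of arrays limits the precision. The labels do not say whether the ES or TS replicates were separate cultures, so p-values measure only the spread between these samples. The fit was tested on simulated log ratios of 40616 probes with independent noise and 50 probes changed at each of 4 fold sizes. Background correction, loess and bounds were not part of the simulation. Far fewer probes were changed in it than were called in these data, so its false calls are no error rate of the counts reported here. At 1.5-fold the fit recovered 47 for TS against ES cells, 45 for placenta against embryo, 45 for ES cells against embryo, 49 for TS cells against placenta and 41 for the interaction. At 2-fold it recovered 49, 49, 50, 50 and 49 in that order, and at 4-fold 50, 50, 50, 50 and 49. At 8-fold it recovered 50 in each, and among 40416 unchanged probes it called 14, 11, 10, 16 and 11. Alternatives were the scanner software's processed signals, no offset, median centring, Cy3 alone, Cy3 scaled on spike-in controls, the deposited value table, removal of dim probes, fits of each pair of groups alone, a block for the replicate number, stricter thresholds, the mean of a gene's probes, and leaving out each array in turn.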

Results

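RNA abundance was measured in E12.5 mouse embryos, E12.5 placentas, ES cells and TS cells, with 3 arrays for each of the 4 types. The series set these types side by side to test an array of 60-mer probes that carried 7 yeast spike-in controls. Values are log2 ratios of the sample's Cy3 signal to the Cy5 signal of the common reference, and each difference is given with its standard error from a fit to 3 arrays per group. Across probes, arrays of 1 type correlated at 0.960 to 0.991 and arrays of different types at 0.314 to 0.707, although probes are not independent replicates. The median standard deviation (SD) of a probe was 0.05 for the embryo, placenta and ES arrays and 0.07 for the TS arrays. Cy3 was well above background at 90.1% of spots on the array of TS replicate 3, the lowest, and at 95.2% on that of embryo replicate 2, the highest. Between 23 and 124 Cy3 spots per array were saturated.

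TS cells had more of trophoblast stem cell transcripts and ES cells more of pluripotency transcripts. Elf5, a transcription factor that keeps TS cells dividing, stood at 5.79 ± 0.11 (SD, n = 3) in TS cells and at 0.25 ± 0.11 in ES cells, a difference of 5.55 with a standard error of 0.09 (adjusted p 1.9e-13). Gata3, another trophoblast factor, differed by 5.39 ± 0.13 (SE) and rose from -3.33 ± 0.03 (SD, n = 3) in ES cells to 2.06 ± 0.37 in TS cells. Lefty1, a secreted inhibitor of Nodal signalling, was lower in TS cells by -5.99 ± 0.09 (SE), at 4.88 ± 0.03 (SD, n = 3) in ES and -1.12 ± 0.07 in TS cells. The pluripotency factor Pou5f1 was lower by -2.74 ± 0.06, at 2.80 ± 0.13 (SD, n = 3) in ES cells and 0.05 ± 0.06 in TS cells, and its processed Cy3 in TS cells was 5.04% of that in ES cells, a wider gap than the ratio gives. Sox2, which both stem cell types are known to use, did not pass, at 5.78 ± 0.04 in ES and 5.56 ± 0.12 in TS cells (adjusted p 0.066), although in processed Cy3 alone its TS signal was 47.9% of the ES signal. The pluripotency marker Zfp42 was high in both, at 5.20 ± 0.03 in ES and 4.66 ± 0.04 in TS cells. In processed Cy3 alone its TS signal was 15.7% of the ES signal, again a wider gap.

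Other genes with the largest TS excess were the natriuretic peptide gene Nppb (4.98), the homeobox gene Irx3 (4.98, with Cy3 well above background on 2 of 3 ES arrays), Xlr4b (4.59), Tmem114 (4.08), the protease gene Htra1 (3.96) and Morc4 (3.92). On the ES side were the germ cell gene Morc1, lower in TS cells by at least 72.3-fold, the neuronal stathmin Stmn2 (-5.56), the Y-linked Eif2s3y, by at least 34.3-fold, Rpl39l (-4.89), the threonine dehydrogenase gene Tdh (-4.82), Trh (-4.66) and Tcl1 (-4.42). Dppa3, a germ cell and pluripotency gene, was lower by at least 115-fold. Cdx2, a trophectoderm factor, was higher in TS cells by 0.63 ± 0.06, while Fgfr2, which encodes the receptor for the FGF4 that sustains TS cells, was higher by 0.24 ± 0.05. With Cy3 scaled on spike-in controls Fgfr2 stood at -0.11 and did not pass (adjusted p 0.874). Fgf4 itself was lower by -0.14 ± 0.04. The mature placental genes Tpbpa and Prl3b1 did not pass, with adjusted p 0.33 and 0.90, nor did Esrrb at 0.24 or Hbb-y at 0.94.

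In all, 14110 probes differed between TS and ES cells, 6727 higher and 7383 lower in TS cells, or 1873 and 3203 with Cy3 scaled on spike-in controls. Of the 14110, 7057 had no name. They represented 5812 named genes, 2936 higher and 2876 lower, with 563 higher and 499 lower by at least 2-fold. Among 889 genes with at least 2 called probes, 39 had probes called in opposite directions.

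Of 23 measured trophoblast stem and early trophectoderm genes, 20 were higher in TS cells and none lower, with a median of 2.03, and 21 passed when adjusted over the list alone. Beside Elf5 and Gata3 these included Id2 (3.66) and the keratin gene Krt8 (3.05). Of 33 pluripotency genes, 23 were lower in TS cells and 2 higher, with a median of -0.89, or 25 and 3 adjusted over the list alone, and Spp1 (-3.31) was among the former. Both calls held with the estimated correlation, at adjusted p 0.00255 and 0.0210. Of 33 cell cycle genes, 22 were lower and 2 higher in TS cells, with replication licensing genes Mcm3 (-1.39), Mcm4 (-1.36) and Mcm5 (-1.23) and the spindle kinase gene Ttk (-1.65) among the lower, or 22 and 3 adjusted over the list alone. Of 36 other placental trophoblast genes, 13 were higher and 2 lower on both counts, with Flt1 (2.87), Esx1 (2.67) and Mmp9 (2.29) higher and Plac8 (-4.41) lower, and a median of only 0.08. These last 2 lists passed with the preset correlation, at adjusted p 1.55e-05 and 0.0239, but with the estimated correlation both had an adjusted p of 0.575.

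The other 15 lists did not pass between TS and ES cells, though single members did. Imprinted genes went both ways, with the growth inhibitor gene Cdkn1c (2.10) and Igf2 (1.17) higher and Impact (-3.40) and Snrpn (-2.20) lower among 5 higher and 11 lower of 34. The basement membrane genes Col4a1 (2.50) and Sparc (2.49) and the hormone receptor gene Pth1r (2.01) were among 6 higher endoderm genes of 16, while Lama1 (-1.93) was among 3 lower. Neural genes were mixed, with Pou3f3 (2.15) higher and Dpysl3 (-1.90) and Neurod1 (-2.32, TS cells well above background on 2 of 3 arrays) lower among 5 higher and 9 lower of 31. Of 16 genes of FGF and MAP kinase feedback, 8 were higher in TS cells, such as Errfi1 (3.02), Fos (1.65) and Myc (1.59 ± 0.24, with TS replicate 3 at -1.15 beside 0.09 and -0.01), and 5 lower, such as Etv5 (-1.67). Hox genes showed 5 higher and none lower of 24, with Hoxa7 (1.14) and Hoxa1 (1.09), and cartilage, limb and mesenchyme genes 6 higher and 4 lower of 27, with Tbx15 (3.53) and Sox9 (1.13). Muscle genes included Acta1 (-2.35) and Mylpf (-2.20), with 4 higher and 6 lower of 29. Of the 7 sex-linked genes, 4 were lower in TS cells and none higher, with Ddx3y (-2.77) beside Eif2s3y, and the list had an adjusted p of 0.0698. Sex was not part of the fit, so at these genes it cannot be told apart from lineage.

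Lists of differentiated and blood-borne cells were among those that did not pass. The prolactin family had 2 higher of 17, Prl8a9 (0.81) and Prl2a1 (0.39), and the decidua list 2 higher and 1 lower of 20, with Cebpb (2.77) and Alpl (-2.27). Erythroid genes had 1 higher and 5 lower of 23, endothelial genes 5 higher and 3 lower of 19, macrophage and leukocyte genes 2 higher and 3 lower of 21 and plasma protein genes none of 20. Fibroblast matrix genes had 3 higher and 9 lower of 21, with Ccn2 (-1.78) and Tagln (-1.68) lower. Adjusted over the list alone, all 15 counts stayed the same except muscle with 5 higher and cartilage with 7 higher. Median, mean and test differed in sign for the cartilage, endothelial and macrophage lists.

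**Figure D1:**
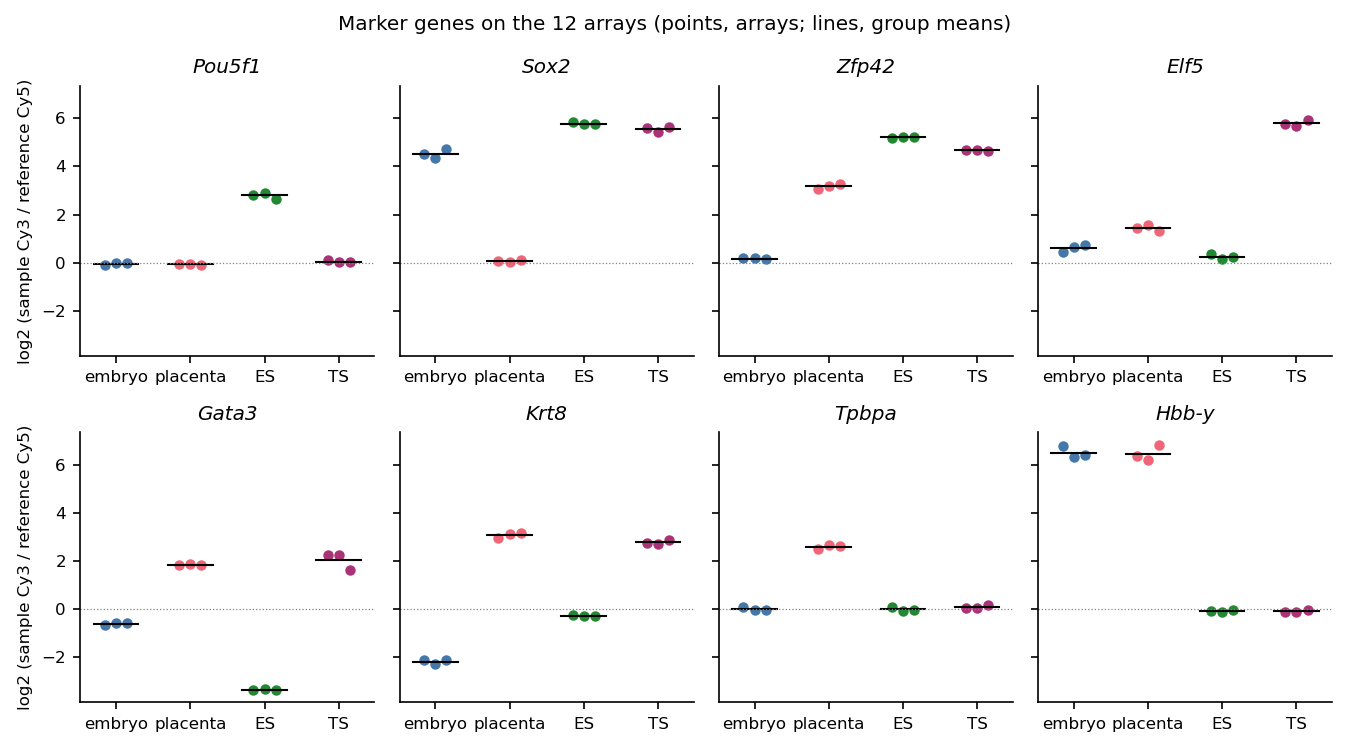
Log2 ratio of the sample's Cy3 signal to the reference's Cy5 signal for 8 markers, with 1 point per array, 3 arrays for each of the 4 sample types and a line at each mean. Pou5f1 stood at 2.80 in ES cells and near 0 in the other types, Elf5 at 5.79 in TS cells, and Hbb-y at 6.51 in embryo and 6.46 in placenta.

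The placenta had more than the embryo of prolactin family and other trophoblast transcripts. Rhox5, an X-linked homeobox gene, stood at 3.81 ± 0.02 (SD, n = 3) in placenta and -2.82 ± 0.08 in embryo, a difference of 6.63 ± 0.16 (SE). Tpbpb, of the spongiotrophoblast, was higher by a fitted 6.57 (adjusted p 8.6e-16). That value is not exact, as the embryo was well above background on only 1 of 3 arrays and mean Cy5 rose from 16.5 to 584. The cathepsin gene Ctsm was higher by 6.34 ± 0.16, Ceacam13 by 6.07 ± 0.15, and Procr, the gene of the protein C receptor, by 5.96 ± 0.11. On the embryo side the orphan receptor gene Nr2f1 was lower in placenta by -5.04 ± 0.14, the hindbrain factor gene Zic1 by -4.89 ± 0.15 and the cardiac myosin gene Myh7 by -4.81 ± 0.13. Tbx15 (-4.67), Sox2 (-4.48, placenta well above background on 1 of 3 arrays), Kcnmb4 (-4.39), Hes5 (-4.38) and Tfap2b (-4.26) followed.

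Several placental transcripts saturated the scanner on all 3 placenta arrays and yield bounds only. Prl8a9 was higher by at least 696-fold, Prl7a2 by at least 1371-fold, Ceacam11 by at least 973-fold and Prl2b1 by at least 223-fold, and Prl8a6, under the background mark on all 3 embryo arrays, by at least 64.1-fold. For Prl3b1, placental lactogen, the fitted difference was only 1.52. Its mean unscaled Cy3 signal above background was 249 in embryo and 65166, saturated, in placenta, but Cy5 at this probe also rose, from 297 to 45262. The log2 ratio of this probe therefore understates the difference. Tpbpa was higher in placenta by 2.59 ± 0.06, Zfp42 by 2.99 ± 0.05, Gata3 by 2.46 ± 0.13, Elf5 by 0.83 ± 0.09, Fgf4 by 0.28 ± 0.04 and Cdx2 by 0.18 ± 0.06. Both tissues held the yolk sac and liver transcript Afp (adjusted p 0.36), embryonic globin Hbb-y (0.82) and Igf2 (0.66) at levels that did not differ past the threshold, with Afp and Hbb-y saturated on 2 of 3 placenta arrays. Nor did Pou5f1 (0.86), Fgfr2 (0.25) or Esrrb (0.47) pass, the last under the background mark on all placenta arrays.

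Between placenta and embryo 20367 probes differed, 9233 higher and 11134 lower in placenta, or 2858 and 7917 with Cy3 scaled on spike-in controls. Of the 20367, 11017 had no name. These gave 7634 genes, 3819 higher and 3815 lower, with 1038 and 948 of at least 2-fold, and 122 of 1273 genes with at least 2 called probes had probes called in opposite directions.

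Of 17 prolactin family genes, 16 were higher in placenta and none lower, also when adjusted over the list alone, with a fitted median of 4.57, or 4.83 with 8 members at their bound. Of 36 other placental trophoblast genes 31 were higher and 2 lower, with a median of 3.31, and of 23 trophoblast stem and early trophectoderm genes 19 were higher and 2 lower, with a median of 1.64, both counts unchanged when adjusted over the list alone. The last included Krt8 (5.26), Krt18, by at least 34.4-fold, Esx1 (4.40) and Rhox6 (4.92, saturated on 2 of 3 placenta arrays). Of 31 neural genes 28 were lower and 1 higher, with Fabp7 (-4.17), Foxg1 (-4.12) and Stmn2 (-4.00) and a median of -1.54, and of 24 Hox genes 19 were lower and 3 higher, with Hoxa7 (-3.15) and Hoxc6 (-2.49) and a median of -0.84, again the same adjusted over the list alone. These 5 lists passed with the preset correlation and held with the estimated one, with adjusted p from 0.0154 to 0.0197.

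Another 9 lists passed between placenta and embryo with the preset correlation only. Muscle had 23 lower and 1 higher of 29, with Acta1 (-4.23), Tnnc2 (-3.55) and Myl2 (-3.04), and cartilage, limb and mesenchyme 20 lower and 2 higher of 27, with Twist1 (-4.14), Shox2 (-3.57) and Msx1 (-3.23). Cell cycle genes had 27 lower and 1 higher of 33, among them Ccna2 (-1.46), Mcm4 (-1.28) and Bub1 (-1.23). The fibroblast matrix list had 13 lower and 4 higher of 21, with Vim (-2.15) lower and Sparc (1.74) higher. Erythroid genes had 15 lower and 3 higher of 23, with Hemgn (-3.91), Tal1 (-1.48) and Spta1 (-1.09) lower and the transferrin receptor gene Tfrc (1.94) higher. Macrophage and leukocyte genes had 14 lower and 3 higher of 21, with the complement genes C1qa (-1.25) and C1qc (-1.20) lower and S100a8 (2.57) and Lcp1 (1.99) higher. With the estimated correlation these lists had an adjusted p of 0.231 for muscle, 0.0761 for cartilage, 0.231 for cell cycle, 0.349 for fibroblast matrix, 0.359 for erythroid and 0.242 for macrophage genes.

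Endothelial genes had 12 higher and 1 lower of 19 in placenta, with Acvrl1 (1.20), Cdh5 (1.04), Clec14a (1.01) and Pecam1 (0.99), endoderm genes 9 higher and 3 lower of 16, with Thbd (1.77), Col4a1 (1.77) and Plat (1.69), and decidua genes 14 higher and 3 lower of 20. The decidual granzyme genes Gzmd (5.55) and Gzmg (4.08) were higher, as were the decidual prolactin Prl8a2 (4.39) and Cebpb (4.69). With the estimated correlation their adjusted p were 0.231, 0.0861 and 0.231. The labels say that decidua were removed to buffer before dissection, which leaves open whether placentas were freed of it. Of the 20 decidua genes measured, 4 were also in another list, and 18 were well above background on all embryo arrays and 19 on all placenta arrays. Medians of these 9 lists in the order given were -1.60, -1.04, -0.85, -0.72, -0.53, -0.30, 0.23, 0.44 and 1.11, and -1.59 for muscle and -1.07 for cartilage with members at their bound. Adjusted over the list alone, the counts changed for muscle (2 higher), erythroid (4 higher) and macrophage genes (4 higher).

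Not passing were pluripotency genes, with 14 higher and 10 lower of 33, imprinted genes with 13 higher and 16 lower of 34, plasma protein genes with 3 higher and 9 lower of 20, FGF feedback genes with 4 higher and 9 lower of 16, and sex-linked genes with 1 higher of 7. Adjusted over the list alone, plasma protein genes had 11 lower and the others were unchanged. Imprinted genes that differed included Slc22a18 (3.66) on the placental side and Nap1l5 (-2.23), Ndn (-1.95) and Asb4 (-1.86, from 2 embryo arrays) on the embryo side. The plasma protein genes Serpina6 (-2.81), Itih2 (-2.40) and Ambp (-1.54) were lower in placenta, and Amn (2.15), of visceral endoderm, was higher. Median, mean and test differed in sign for the imprinted and sex-linked lists.

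**Figure D2:**
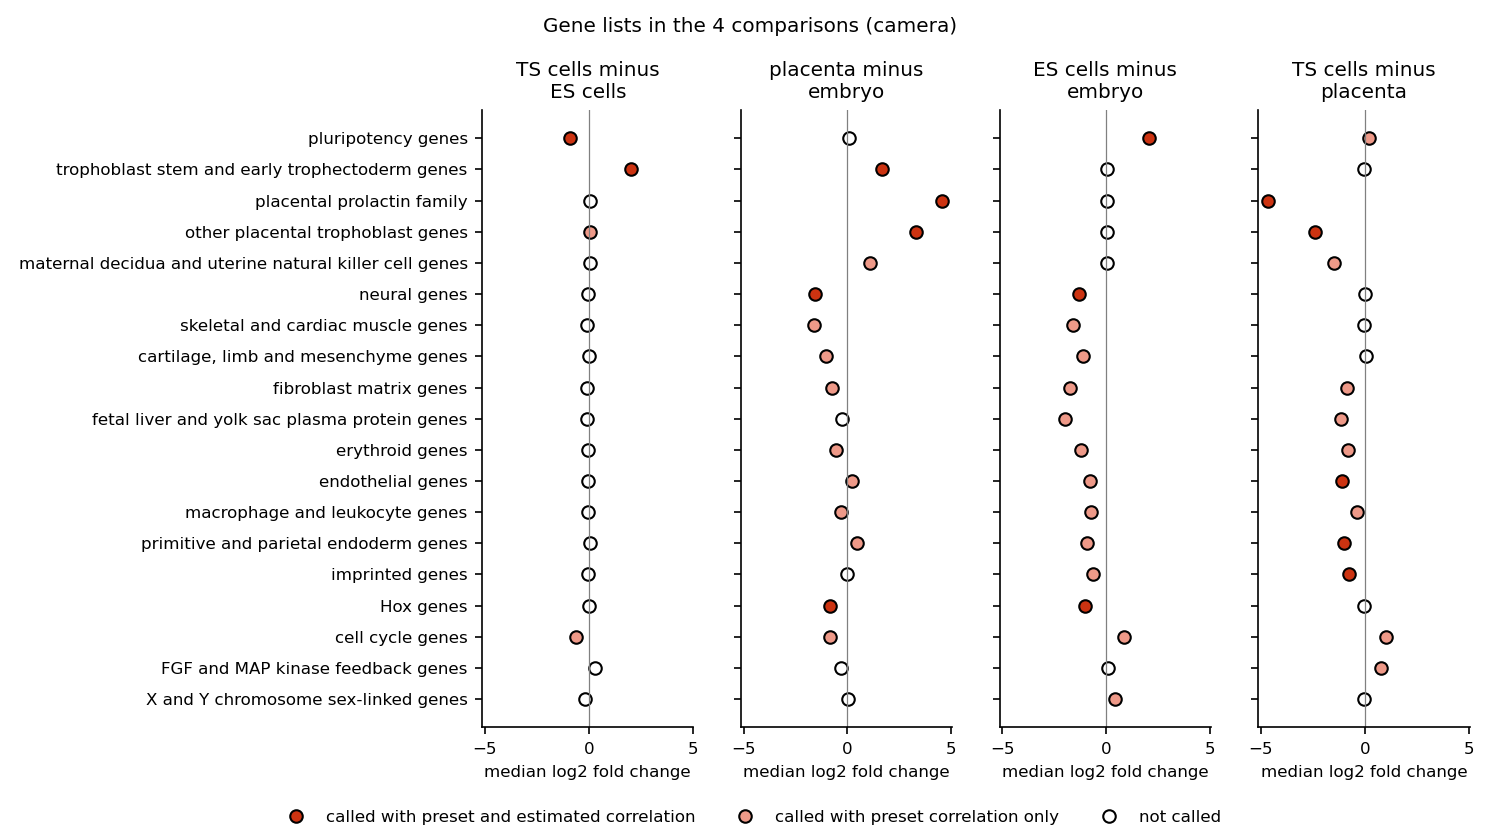
Median log2 difference of each of the 19 gene lists in the 4 comparisons, in log2 units. Dark red points passed with both the preset and the estimated correlation, light ones with the preset correlation only and white ones with neither, and the prolactin family reached 4.57 between placenta and embryo against 0.06 between TS and ES cells.

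ES cells had more of pluripotency transcripts than the whole embryo and less of neural and Hox transcripts. Zfp42 was higher in ES cells by 5.03 ± 0.05 (SE, n = 3 per group), Lefty1 by 5.16 ± 0.09, the polycomb gene Cbx7 by 5.55 ± 0.11, the ES cell Ras gene Eras by 4.87 ± 0.31, Rhox5 by 4.84 ± 0.16, and Morc1 by at least 82.7-fold. On the embryo side Afp was lower in ES cells by at least 556-fold, Hbb-y by -6.57 ± 0.14, the growth regulator gene Dlk1 by -5.79 ± 0.09, the matrix gene Postn by -5.50 ± 0.10, Clmp by -5.04 ± 0.10 and Zic1 by -5.03 ± 0.15. The Hbb-y ratio understates the difference, as mean Cy5 at its probe rose from 108 in ES cells to 837 in embryo. Pou5f1 (2.85), Sox2 (1.25) and Fgf4 (0.40) were higher in ES cells, and Gata3 (-2.73), Igf2 (-0.87), Elf5 (-0.36) and Cdx2 (-0.19) lower. With Cy3 scaled on spike-in controls Fgf4 turned to -0.34 and did not pass (adjusted p 0.315). Tpbpa (adjusted p 0.97), Prl3b1 (0.86) and Fgfr2 (0.13) did not pass, and Esrrb was higher by 0.35, with the embryo well above background on 1 of 3 arrays.

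Here 22908 probes differed, 10616 higher and 12292 lower in ES cells, but 1227 higher and 28918 lower with Cy3 scaled on spike-in controls. Of the 22908, 12930 had no name, and the others gave 8165 genes, 3939 higher and 4226 lower. At least 2-fold differences were found for 816 and 1128 genes, and 231 of 1356 genes with at least 2 called probes had probes called in opposite directions. Of 33 pluripotency genes 30 were higher and 1 lower in ES cells, with a median of 2.07, or 31 and 1 adjusted over the list alone. Neural genes had 25 lower and 2 higher of 31, with Fabp7 (-4.74), Lhx2 (-4.02) and Foxg1 (-3.92), and Hox genes 18 lower and 1 higher of 24, with Hoxa10 (-4.08) and Hoxd4 (-2.64), both the same adjusted over the list alone, with a median of -1.32 for the former and a mean of -1.20 for the latter. These 3 lists held with the estimated correlation, at adjusted p 0.0136, 0.0411 and 0.0411.

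Another 11 lists passed between ES cells and embryo with the preset correlation and lost that call with the estimated one, at adjusted p from 0.0806 for the macrophage and endoderm lists to 0.272 for plasma proteins. Lower in ES cells were 24 of 29 muscle genes, with Myh7 (-4.49) and Tnnt2 (-3.61, ES cells well above background on 1 of 3 arrays), 20 of 27 cartilage, limb and mesenchyme genes, with Tbx15 (-4.62) and Twist1 (-4.05), and 16 of 21 fibroblast matrix genes, with Dcn (-4.73), Lum (-4.39) and Pdgfra (-3.88). Lower as well were 18 of 20 plasma protein genes, with Itih2 (-3.60) and Apoa1 (-2.98, ES cells well above background on 2 of 3 arrays), and 20 of 23 erythroid genes, with Hemgn (-4.88) and Tal1 (-3.94). The same held for 13 of 19 endothelial genes, with Icam2 (-2.13) and Emcn (-1.95), 16 of 21 macrophage and leukocyte genes, with C1qa (-2.67) and Ctss (-2.19), 11 of 16 endoderm genes, with Sox7 (-2.16, ES cells well above background on 1 of 3 arrays) and Pth1r (-1.71), and 21 of 34 imprinted genes, with Asb4 (-4.71, from 2 embryo arrays) and Ndn (-3.16). Plasma protein genes had a mean of -2.08, and medians of the other 8 in this order were -1.58, -1.13, -1.76, -1.22, -0.77, -0.73, -0.92 and -0.64, or with members at their bound -1.44 for muscle, -1.04 for cartilage, -1.15 for erythroid and -0.55 for imprinted genes. Higher in ES cells were 28 of 33 cell cycle genes, with Orc1 (2.42), Nek2 (1.78) and Cdt1 (1.57) and a median of 0.85. Also higher were 5 of 7 sex-linked genes, with Eif2s3y (2.07), Usp9y (1.77), Ddx3y (0.67) and Uty (0.41) and a median of 0.41 that turned to -0.07 with Cy3 scaled on spike-in controls, as did Ddx3y (adjusted p 0.835).

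Members of these 11 lists that went the other way numbered 1 for muscle, 2 for cartilage, 2 for fibroblast matrix, 1 for plasma proteins, 1 for erythroid, 0 for endothelial, 2 for macrophage, 3 for endoderm, 6 for imprinted, 2 for cell cycle and 0 for sex-linked genes. Adjusted over the list alone, the counts changed for cartilage (5 higher), erythroid (2 higher and 21 lower), endothelial (14 lower) and imprinted genes (7 higher). The trophectoderm list did not pass, with 11 higher and 9 lower of 23, such as Tfap2c (2.62), Rhox9 (2.48) and Rhox6 (2.44). Nor did the prolactin family, with 1 higher of 17, Prl7a1 (0.30, or -0.53 at adjusted p 0.117 with Cy3 scaled on spike-in controls), which failed when adjusted over the list alone. Other trophoblast genes had 8 higher and 6 lower of 36, or 7 and 6 adjusted over the list alone, with Plac8 (2.87) and Phlda2 (1.77). Decidua genes had 3 higher and 5 lower of 20, with Alpl (3.24), and FGF feedback genes 8 higher and 4 lower of 16, with Etv5 (2.82), both the same adjusted over the list alone. For the decidua list median and test differed in sign.

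TS cells had less of prolactin family and other placental trophoblast transcripts than the placenta, while single stem cell genes were higher. Sox2 was higher in TS cells by 5.50 ± 0.09 (SE, n = 3 per group), with placenta well above background on 1 of 3 arrays, Elf5 by 4.35 ± 0.09, Tmem114 by 4.21 ± 0.06 and the nuclear receptor gene Nr0b1 by 3.71 ± 0.10. Dppa4 was higher by 3.62 ± 0.07, at 3.32 ± 0.06 (SD, n = 3) in TS cells, -0.30 ± 0.08 in placenta and 3.38 ± 0.09 in ES cells, and Tbx15 by 3.59 ± 0.09. Plac8 was lower in TS cells by -6.92 ± 0.07, Ctsm by -6.37 ± 0.16 and Hbb-y by a fitted -6.55, not exact because of saturation on 2 of 3 placenta arrays. Mean Cy5 at the Hbb-y probe also rose, from 142 in TS cells to 1167 in placenta. Prl7a2 was lower by at least 1354-fold, Tpbpb by at least 717-fold and Afp by at least 756-fold, the last saturated on 2 of 3 placenta arrays. Tpbpa was lower by -2.50 ± 0.06 and Prl3b1 by at least 380-fold, while Zfp42 was higher by 1.49, Igf2 by 0.33 and Cdx2 by 0.26. The last pair turned to -0.27 and -0.54 with Cy3 scaled on spike-in controls and did not pass then (adjusted p 0.434 and 0.115). Gata3 (adjusted p 0.22), Pou5f1 (0.11), Fgfr2 (0.38) and Fgf4 (0.67) did not pass.

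Between TS cells and placenta 19506 probes differed, 8991 higher and 10515 lower in TS cells, but 1060 higher and 27014 lower with Cy3 scaled on spike-in controls. Of the 19506, 10494 had no name, and the others gave 7370 genes, 3391 higher and 3979 lower, with 630 and 997 of at least 2-fold. In opposite directions were probes of 121 of 1240 genes with at least 2 called probes. Lower in TS cells were 16 of 17 prolactin family genes, such as Prl8a9, by at least 452-fold, with a median of -4.66, or -4.74 with members at their bound. So were 29 of 36 other trophoblast genes, such as Ceacam11, by at least 943-fold, with a median of -2.42, or -2.45 with members at their bound. Of 19 endothelial genes 17 were lower, with Icam2 (-2.61), Clec14a (-2.49) and Emcn (-2.16) and a median of -1.12, of 16 endoderm genes 11, with Plat (-3.56, TS cells well above background on 2 of 3 arrays), Thbd (-2.20) and Lama1 (-2.16) and a median of -1.02, and of 34 imprinted genes 21, with Dcn (-6.22), Dlk1 (-5.26) and Slc22a18 (-2.33) and a median of -0.77. All 5 lists held with the estimated correlation, at adjusted p from 0.0326 to 0.0482.

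Higher in TS cells than in placenta were 29 of 33 cell cycle genes, with Nek2 (2.28), Bub1 (2.09) and Cdc20 (1.89) and a median of 1.00, and 12 of 16 FGF feedback genes, with Egr1 (2.40), Etv5 (2.14) and Etv4 (1.47) and a median of 0.78. Pluripotency genes had 18 higher and 4 lower of 33, with Dnmt3b (3.34), and a median of 0.17 that turned to -0.43 with Cy3 scaled on spike-in controls. Lower were 16 of 20 decidua genes, with Gzmd, by at least 227-fold, and Angpt2 (-3.91), 17 of 21 fibroblast matrix genes, with Lum (-3.47) and Pdgfrb (-3.12), and 16 of 20 plasma protein genes, with Trf (-3.55), Apoa1 (-3.50, TS cells well above background on 2 of 3 arrays) and Fgg (-3.12). Also lower were 17 of 23 erythroid genes, with Hba-x (-2.74, saturated on 2 of 3 placenta arrays), Tal1 (-2.52) and Tfrc (-2.15), and 16 of 21 macrophage and leukocyte genes, with S100a8 (-4.29), C1qa (-1.57) and Ctss (-1.55). Medians of these last 5 were -1.51, -0.86, -1.17, -0.82 and -0.39, and -0.79 for erythroid genes with members at their bound. These 8 lists lost their call with the estimated correlation, at adjusted p from 0.0795 for pluripotency to 0.375 for plasma proteins.

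Members that went the other way between TS cells and placenta numbered 0 for prolactins, 4 for other trophoblast, 1 for endothelial, 2 for endoderm and 3 for imprinted genes. They numbered 1 each for cell cycle, FGF feedback, decidua, fibroblast matrix and macrophage genes, 0 for plasma proteins and 2 for erythroid genes. The lists that did not pass were trophectoderm genes with 7 higher and 10 lower of 23, where Bmp8b (1.89) and Id2 (3.00) were higher and Gata2 (-1.38) lower, and neural genes with 9 higher and 12 lower of 31, where Pou3f3 (2.77) was higher and Lhx2 (-2.06) lower. Others were muscle with 5 higher and 8 lower of 29, where Nppb (3.34) was higher and Myl4 (-4.20) lower, cartilage with 9 and 9 of 27, where Msx1 (1.62) was higher and Postn (-4.82, TS cells well above background on 2 of 3 arrays) lower, Hox genes with 5 higher and 8 lower of 24, where Hoxa1 (1.08) was higher and Hoxa10 (-2.78) lower, and sex-linked genes with 2 higher and 3 lower of 7, where Usp9y (1.15) was higher and Ddx3y (-1.86) lower. Adjusted over the list alone, the only count of these 19 lists that changed was that of plasma proteins, with 18 lower. Median, mean and test differed in sign for the trophectoderm and cartilage lists.

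The TS minus ES and the placenta minus embryo differences share no array. Both set the trophoblast side against embryonic material, though genes of other cells were also higher in placenta. Among 41006 probes, 3423 were higher in both, where independent lists would share 1515, and 3840 were lower in both, against 2005. Opposite calls were made for 3285 probes, against 3489 for independent lists, and the 7263 calls in 1 direction compare with 3519. The differences correlated at 0.312 across probes. Krt8, Esx1, Gata3, Elf5 and Cebpb were among the genes higher in both, while Tbx15 and Zic1 were higher in TS cells and lower in placenta. Plac8 and Zfp42 were lower in TS cells and higher in placenta. ES against embryo and TS cells against placenta, the comparisons of a cell line with a tissue, were both higher for 5269 probes against 2328 for independent lists, both lower for 6071 against 3152 and opposite for 3345 against 5417, with a correlation of 0.372.

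**Figure D3:**
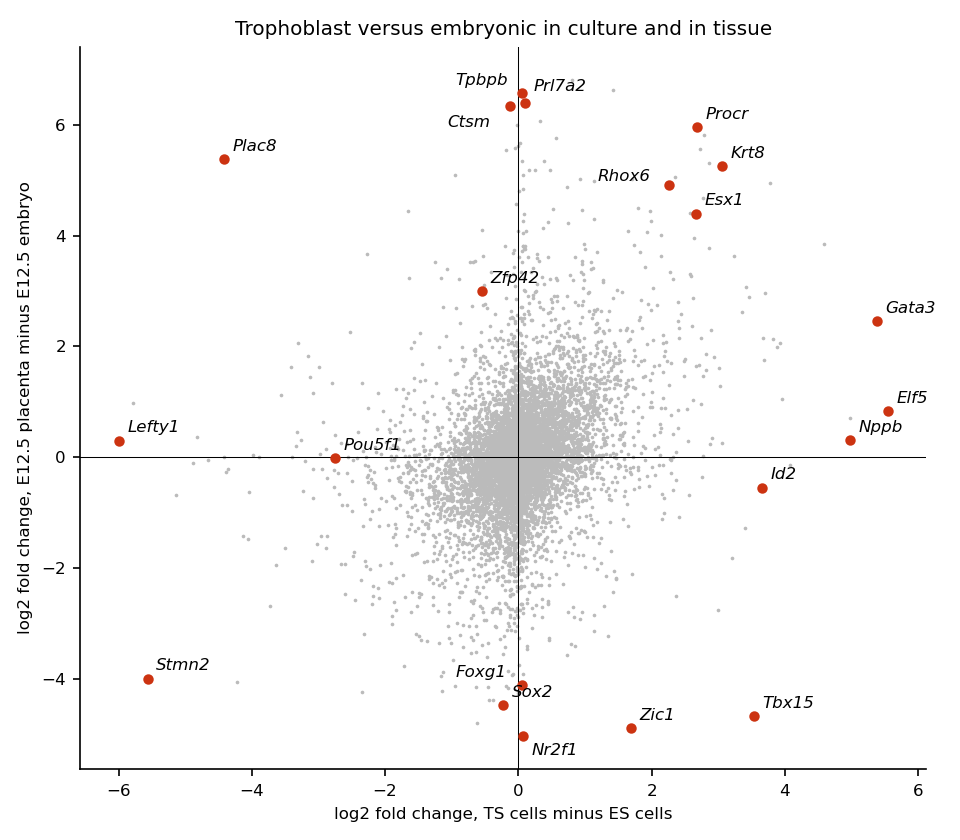
Fitted log2 difference of TS against ES cells on the horizontal axis and of placenta against embryo on the vertical axis, with 1 point per gene and labels on 21 genes. Elf5 lies at 5.55 and 0.83, Tbx15 at 3.53 and -4.67, and Lefty1 at -5.99 and near 0.

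The spike-in controls spanned a wide range of brightness, and the 4 between the brightest pair and the dimmest kept 1 order on 12 of 12 arrays. For all 7 from the brightest, mean log2 processed Cy3 signals, each from 20 spots per array, were 18.7, 18.1, 15.4, 12.8, 10.1, 9.08 and 6.09. The brightest was saturated at all of its 240 spots and the next at 44, so neither their order nor their distance is measured, and the dimmest was well above background at only 113 of 240. The SD between spots of a control on an array averaged 0.00, 0.23, 0.35, 0.46, 0.83, 0.60 and 0.60 in the same order, and the SD between arrays was 0.24, 0.53, 0.74, 0.58, 0.08, 0.33 and 0.47. The labels give 10 spots per control, whereas the files hold 20. The amounts added are not in the labels, so no copy number was computed.

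**Figure D4:**
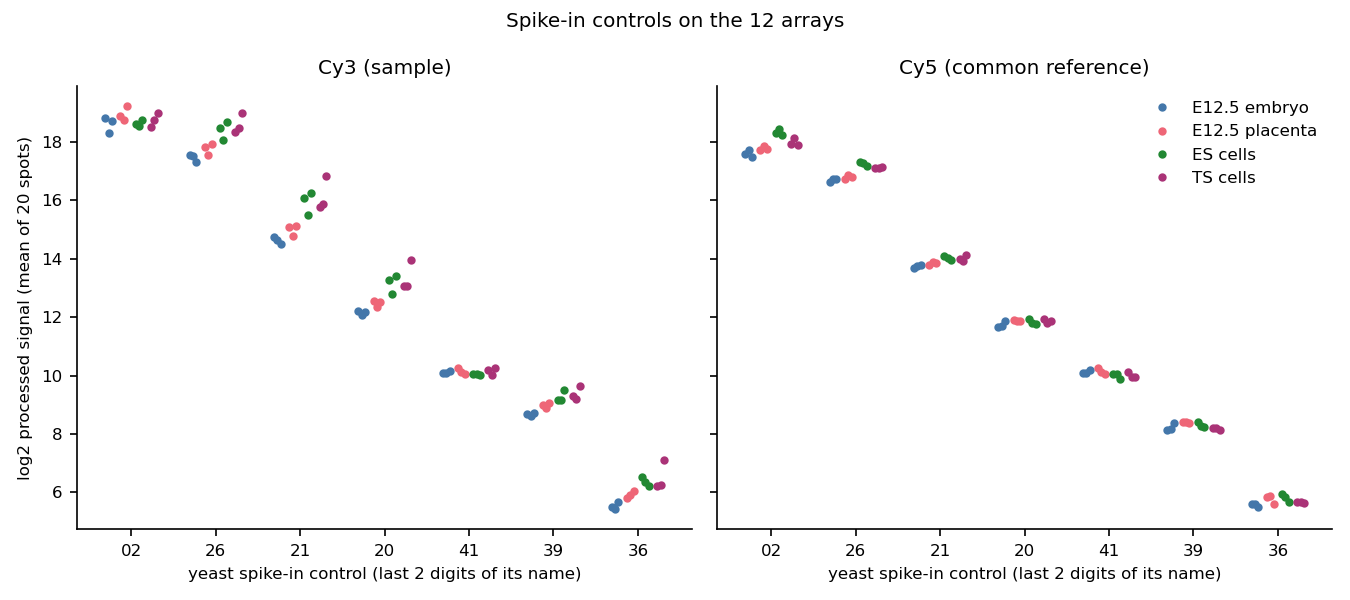
Mean log2 processed signal of 7 spike-in controls over 20 spots on each array, for Cy3 and Cy5, with 1 point per array coloured by sample type. The brightest control averaged 18.7 and the dimmest 6.09 in Cy3.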

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

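The regroupings of the arrays were planned, and the tests that reordered residuals and those of the pluripotency genes in TS cells were chosen after the results were seen. It was tested directly whether the TS minus ES difference equals the placenta minus embryo difference. This sets stem cell lines against whole tissues, and endothelial (12 of 19) and decidua genes (14 of 20) were also higher in placenta. The interaction therefore mixes culture with stage and cell composition. At 17505 probes, of which 9240 had no name, the TS minus ES difference and the placenta minus embryo difference were unlike, 9321 with the larger value in the cell lines and 8184 with the smaller, or 3979 and 2314 with Cy3 scaled on spike-in controls. Of 100 groupings of the 12 arrays into 4 groups of 3, the real one included, only 1 called as many probes, the real one, and the highest other count was 2828. Every other grouping mixes sample types, so this leaves the interaction itself untested. The residuals of a fit without the interaction were put in 100 orders, the real one included. This keeps the differences of culture from tissue and of TS cells and placenta from ES cells and embryo. Only the real order called as many and the highest other count was 0. Those residuals still hold the interaction, which any other order spreads over the groups as noise. Low counts in other orders were therefore likely in advance, and no conclusion on chance is drawn. For the single comparisons, 10 splits of 3 against 3 are too few for a share under 0.05. Their real counts were 14110, 20367, 22908 and 19506 for TS against ES cells, placenta against embryo, ES cells against embryo and TS cells against placenta, and the highest others 0, 0, 1 and 0, so that 1 of 10 splits, the real one, called as many in each.

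Among named genes, the T-box gene Tbx15 had the largest positive interaction, 8.20 ± 0.13 (SE), from 3.53 for TS against ES cells and -4.67 for placenta against embryo. Zic1 followed at 6.58 ± 0.21, the homeobox gene Meis1 at 5.75 ± 0.08, Nr2f1 at 5.11 ± 0.21 and the signalling gene Wnt6 at 5.02 ± 0.09. They did not share 1 pattern. Wnt6 was highest in TS cells, at 2.59 ± 0.12 (SD, n = 3) beside 0.96 ± 0.06 in embryo, whereas Nr2f1 was equally low in TS and ES cells, at -3.11 ± 0.27 and -3.18 ± 0.19, the latter from 2 arrays, and stood at 2.32 ± 0.14 in embryo and -2.72 ± 0.21 in placenta. Negative interactions were those of Plac8 at -9.80 ± 0.09, which was high in placenta and ES cells, Lefty1 at -6.29 ± 0.12, which was high in ES cells, and Ctsm at -6.46 ± 0.23, which was high in placenta. Fitted values of -6.75 for Morc1, high in ES cells, and -6.52 for Tpbpb, high in placenta, are not exact, and neither is their rank. Morc1 was under the background mark on all embryo and TS arrays, and Tpbpb on all ES and TS arrays and 2 of 3 embryo arrays.

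Of the 19 gene lists, 14 passed for the interaction with the preset correlation, 5 of them also with the estimated correlation. The prolactin family had a fitted median interaction of -4.60, or -4.77 with 8 members at a bound in at least 1 of the 2 differences, with 16 of 17 members negative and none positive, other placental trophoblast genes -2.50, with 30 of 36 negative and 3 positive, and pluripotency genes -0.80, with 24 of 33 negative and 3 positive. Neural genes had 1.12, with 26 of 31 positive and 2 negative, and Hox genes 0.96, with 19 of 24 positive and none negative. These 5 lists held with the estimated correlation, at adjusted p from 0.0209 to 0.0277. Another 9 passed with the preset correlation only. They were decidua genes with a median of -1.18, muscle 1.58 (1.52 with members at a bound), cartilage 0.85 (0.84), fibroblast matrix 0.62, erythroid 0.58, endothelial -0.21, macrophage 0.20, FGF feedback 0.53 and sex-linked genes -0.62. With the estimated correlation their adjusted p ran from 0.0876 for cartilage to 0.542 for FGF feedback genes.

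Several pluripotency genes had TS signals near those of ES cells, which may point to ES cells among the TS cells or to genes that both stem cell types use. Processed Cy3 in TS cells was 47.9% of that in ES cells for Sox2, 87.4% for Dppa4 and 129% for Dnmt3b, genes singled out after their values were seen. ES cells would bring their other abundant transcripts at a like share, but Pou5f1 stood at 5.04%, Tcl1 at 2.22% and Lefty1 at 0.448%, while Dppa3 was measured only as a bound. This argues against ES cells as the source of the Sox2 and Dppa4 signal. Sox2 is known to be used by both stem cell types. For Dppa4 and Dnmt3b, use by TS cells themselves stays open as a hypothesis, since it was found and tested on the same arrays.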

How the results depend on the processing

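The spike-in scaling and the other alternatives were planned, and of the tests in this part only the correlations of same-number arrays were added after the files were read. Counts kept within 1.5 times their value under 9 of the alternatives, save that the interaction has no fit of a pair of groups alone. Among these were the scanner software's processed signals, no offset, median centring, Cy3 alone, the deposited value table and the replicate block. They gave 10934 to 14435 probes for TS against ES cells, 15602 to 21277 for placenta against embryo, 17897 to 23531 for ES cells against embryo, 15285 to 19561 for TS cells against placenta and 13077 to 17508 for the interaction. A 2-fold minimum, which by construction lowers counts, left 2245, 4407, 4542, 3441 and 4478 in that order, and 834 shared calls of 1 direction in place of 7263. The same minimum left 3375, 6286, 6654, 5039 and 6531 with the scanner software's processed signals, and 3075, 5858, 6151, 4603 and 6022 with no offset. Counts of 2-fold differences and fold sizes therefore depend on the processing. Cy3 scaled on 3 spike-in controls gave 5076 for TS against ES cells, 10775 for placenta against embryo, 6293 for the interaction and 2320 shared calls. It gave 30145 for ES cells against embryo and 28074 for TS cells against placenta, 28918 and 27014 of them lower in the cell lines, with shifts of the median of all probes of -0.20, -0.25, -0.92, -0.88 and 0.04 over the 5 comparisons. At 9 values of named genes the sign changed, with a call in only 1 of the 2 settings. Cdx2 (-0.54), Igf2 (-0.27), Gata3 (-0.68), Pou5f1 (-0.91) and Fgfr2 (-1.01), the last 3 called only with this scaling, were then lower in TS cells than in placenta, Fgfr2 in TS than in ES cells (-0.11), and Ddx3y (-0.0725), Fgf4 (-0.34) and Prl7a1 (-0.53) in ES cells than in embryo. Why the controls differed was not tested further than described for them, and the cause was not tested for the lower counts. Leaving out 1 array gave 12677 to 14475, 18755 to 19003, 20958 to 21751, 17402 to 19041 and 16360 to 18579, and 6742 to 7274 shared calls, and no gene reversed. Of 6965 alternative values of named genes, 6871 stayed on the same side of the threshold, 40 of them uncalled with a changed sign, 66 lost the call, 19 gained it and 9 reversed. Of 1805 for lists, 1699 stayed on the same side, 24 of them uncalled with a changed direction, 77 lost the call, 39 of them with the estimated correlation, 28 gained it, 19 of them with fry, and the cartilage list, at 0.0481 for TS cells against placenta, took the other direction with fry, whose test looks at the list alone. Leaving the estimated correlation aside, list calls that changed in at least 1 camera alternative are given with the range of adjusted p over the others. They were macrophage (0.0201 to 0.4), erythroid (0.00246 to 0.0899) and endothelial genes (0.00459 to 0.1) for placenta against embryo, sex-linked genes for ES cells against embryo (0.0193 to 0.077), and for the interaction macrophage (0.0314 to 0.184), endothelial (0.0313 to 0.107), erythroid (0.00731 to 0.24), fibroblast (0.0205 to 0.0709), FGF feedback (0.00312 to 0.057) and sex-linked genes (2.45e-05 to 0.0606). Calls were gained with spike-in scaling by neural genes (0.00285 to 0.205) and sex-linked genes (1.02e-10 to 0.112) for TS against ES cells, trophectoderm genes for ES cells against embryo (0.0399 to 0.467) and sex-linked genes for TS cells against placenta (0.00976 to 0.88), the second also under 5 other alternatives. Single arrays decided some. Without placenta replicate 1 or 2 the macrophage list of placenta against embryo stood at 0.0534 or 0.0559, without embryo replicate 1 the sex-linked list of ES cells against embryo at 0.0549, and without TS replicate 1 the FGF feedback interaction at 0.057. The sex-linked interaction lost its call without embryo replicate 1 (0.0505) or TS replicate 3 (0.0606), the fibroblast one without ES replicate 2 (0.0559), the endothelial one without embryo replicate 1 (0.054), placenta replicate 3 (0.0593) or TS replicate 3 (0.0855), and the macrophage one without any of 7 arrays (0.0505 to 0.0696), namely embryo 1, placenta 1 and 2, ES 1 and 2, and TS 1 and 3. The labels pool embryos and placentas by litter but do not say that a number marks a litter, so the pairing is not established. Deviations of same-number placenta and embryo arrays from their group means correlated at 0.163, 0.0691 and 0.141, each the highest for that placenta, and of TS and ES arrays at -0.0444, 0.112 and 0.180. With a replicate block 12809 and 21036 probes passed in these comparisons, and the sex-linked list passed for TS against ES cells (0.0307). A block for slide could not be fitted, since each slide held 1 array. The slide numbers in the labels run from the tissues to the ES cells and then the TS cells. A drift over slides therefore cannot be told apart from cell line against tissue, or from TS against ES cells. The headers give 1 day for the extraction by the scanner software, which does not give the scan day. No block for scan day was fitted, so a scan batch is not excluded. Signal over background limits the dimmest genes, which are given as bounds.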

Other observations

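All tests of this part were chosen after the results were seen. Of 4 Y-linked transcripts, 3 were lowest in TS cells. Eif2s3y stood at 2.45 ± 0.10 (SD, n = 3) in ES cells, 0.38 ± 0.41 in embryo and -0.30 ± 0.69 in placenta, and it was under the background mark on all 3 TS arrays, as was Uty. Ddx3y stood at -2.33 ± 0.14 in TS and 0.44 ± 0.08 in ES cells, but the probe for Usp9y, also Y-linked, stood at 1.46 ± 0.09 in TS and 1.66 ± 0.10 in ES cells. At Y-linked genes neither TS against ES cells nor the interaction can separate lineage from the sex of the lines, which was not fitted. Imprinted growth regulators differed in which sample they marked. Cdkn1c stood at 5.15 ± 0.22 in embryo, 5.34 ± 0.15 in placenta, 4.49 ± 0.11 in TS and 2.39 ± 0.13 in ES cells, whereas Phlda2 stood at 2.90 ± 0.09, 2.85 ± 0.18 and 2.85 ± 0.01 in placenta, TS and ES cells and at 1.08 ± 0.12 in embryo. Impact was low in TS cells alone, at -2.99 ± 0.18 beside -0.76 ± 0.06 in embryo, -0.75 ± 0.11 in placenta and 0.41 ± 0.07 in ES cells.

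TS replicate 3, the only one marked p35/22, had 45 probes at least 2-fold from the mean of replicates 1 and 2, 20 higher and 25 lower, while replicates 1 and 2 were that far apart at 6 probes. The pluripotency gene Eras stood at 2.89 on it and at 1.35 and 1.27 on the others, and Myc at -1.15 beside 0.09 and -0.01, both genes singled out after their values were seen. Counts like these were 33 for placenta replicate 3 and 30 for embryo replicate 3, the pools of 3, and from 0 to 17 for the other arrays. With 1 array so marked, the cause was not tested.

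Where sample signals differed strongly, the signal of the common reference differed as well. Over unsaturated probes with a Cy3 difference above 5000 units and a dim reference, Cy5 moved the same way as Cy3 in 99.5% of 199 comparisons, whichever group was brighter, with median changes of 3.31% to 6.51% of the Cy3 change. A candidate explanation for these probes is carry-over of Cy3 signal into the Cy5 channel. At Prl3b1, saturated and so left out, mean Cy5 rose from 297 in embryo to 45262 in placenta. Its true Cy3 signal in placenta is unknown, so no share can be computed there, and that rise stays unexplained. Reference RNA that differed between arrays was looked for in 2687 comparisons of probes bright in Cy5 and near equal in Cy3, of which 0.0372% differed 2-fold in Cy5. Their median log2 Cy5 differences were 0.24 for TS minus ES cells, -0.06 for placenta minus embryo, -0.16 for ES cells minus embryo and 0.15 for TS cells minus placenta. These probes are bright and the threshold was 2-fold, so smaller differences of the reference at dim probes stay open. No biological explanation was tested, as the reference was common to all groups.

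Most of the 7 spike-in controls were brighter in processed Cy3 on the 6 cell line than on the 6 tissue arrays, with log2 differences of -0.10, 0.89, 1.24, 0.94, -0.02, 0.52 and 0.72 from the brightest control to the dimmest. Exact two-sided permutation p was 0.00216 (adjusted 0.00303), the smallest that splits of 6 against 6 can give, for 5 of them, and 0.517 and 0.714 (adjusted 0.604 and 0.714) for the first, which was saturated, and the fifth. Without dye scaling the differences were -0.00, 0.92, 1.05, 0.61, -0.31, 0.13 and 0.15, and only the 3 of at least 0.61 passed, at adjusted exact p 0.00758, 0.00758 and 0.0101, with 0.0758 to 0.177 for the others. A higher Cy3 gain of these arrays alone would raise the other probes too. Their unscaled median log2 Cy3 differed by -0.41, cell lines minus tissues, against 0.60 for the 3 scaling controls on the same scale. With the fifth control the difference for 4 was 0.37. The fifth was left out of the scaling because 1 of its 240 spots was not well above background. The median of the other probes also depends on the amount and makeup of the labelled RNA, so a higher gain beside such changes stays open. A larger share of spike-in RNA in the labelled cell line RNA could raise the 3 by the 0.60 seen unscaled, or 0.90 processed (0.67 for the 4), but the fifth did not rise and the amounts are not in the labels, so this and a true difference in RNA content per sample cannot be told apart. A drift over the slides, whose numbers run from tissues to cell lines, cannot be told apart from these either.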
